A study of Saccharomyces cerevisiae with 75 samples.

How the data were processed

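Relative RNA levels in Saccharomyces cerevisiae were measured on 2-colour spotted arrays that the series describes as specific for splicing. Per the labels, total RNA was extracted with acid phenol and copied into cDNA with aminoallyl dUTP, and each array compared 2 strains, one in Cy5 and one in Cy3. Of the 75 arrays, 73 compared deletion strains with a matched wild type or with each other, in 21 groups set by the strains, the temperature and the time. The other 2 arrays compared the splicing mutant prp2-1 with prp5-1 and with prp8-1.

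The deposited values are log2 ratios. The value table states no scale, and log2 was taken from the values, whose largest absolute value was 12.04. The scanner settings, background correction and normalization that the authors used are not given in the sources used here. Array medians lay between -0.03 and 0.033, within the limit of 0.1 set for leaving arrays as deposited, so no centring was applied. Dye-flipped arrays of one extract pair ran the same way in the values, with a correlation over probes above 0 in 26 of 36 pairs (median 0.302, range -0.359 to 0.837). The ratio was therefore read the same way in both dye orientations, as the strain named first in each comparison here (the mutant where the other was wild type) over the other, although the titles of dye-flipped arrays name the strains in the opposite order. This direction rests on the values and on the probes of the deleted genes, since the table itself does not state it. The correlation was below 0 in 10 pairs. Among them were all pairs of the hrb1 deletion, replicate 2 of gbp2 deletion at 37 °C and replicate 1 of the double deletion at both temperatures. In 10 pairs the dye difference was larger than the mean of the 2 arrays.

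Each array held 9216 spots, which were 1536 probes printed at 6 positions. The gene table that came with the platform named a gene for 1457 probes, left 79 without a name and gave no probe several genes. All 8742 of its lines matched the reference gene table (assembly R64) by Entrez identifier, and 0 symbols needed an update. These names covered 982 genes, of which 747 had 1 probe, 4 had 2, 222 had 3 and 9 had 4. Between 0.18% and 35.38% of the spots of an array had no value (median 3.9%). The median SD among the 6 spots of a probe was 0.213 over arrays (range 0.123 to 0.781). No scanner intensities were used, so the signal behind each ratio is unknown, and the number of arrays limits the precision. Coordinates are not printed because the sources name no genome build for the probes.

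Spots of a probe were averaged, and the dye-flipped arrays of an extract pair were averaged to 1 value. This gave 37 extract pairs, 36 of them dye-flipped and 1 a single array (npl3 deletion at 37 °C for 30 min, replicate 6). Nothing in the labels says that extract pairs of a group came from separate cultures, so p-values measure only the spread between these extract pairs, which may be partly technical. The array titles define 6 batches, called A to F here. Replicate numbers were given in the order of the samples and pair nothing. All 37 pairs were fitted together with limma (lmFit and eBayes, 17 coefficients and 20 residual degrees of freedom), so comparisons with 1 or 2 pairs borrowed the spread of the others. A probe was tested if at least 50% of the pairs had a value. P-values were adjusted by the Benjamini-Hochberg method over all probes of a comparison, and a probe was called at an adjusted p under 0.05. SE is that of the fit, and SD is that between the extract pairs of a group.

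The groups, the fit, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. That plan held an intron index that needed probe types. Since neither the value table nor the gene table gives them, the plan's own fallback was followed and probes were tested singly. A second measure was added after the layout was seen. For 228 genes (97 for ribosomal proteins, 131 others) the print holds 3 probes in a fixed order, found from spot positions and locus tags alone, with 398 of 399 neighbouring wells in locus-tag order. Neighbouring wells of the same gene always count as ordered. This share therefore checks the order of genes and not that of the probes within a gene. The order rule was settled during a first look at the values of known genes, and the sign of the contrast was chosen after the medians of the probe classes had been seen. The log2 ratio of the second printed probe minus that of the third is called the probe contrast. It was tested with limma as for single probes, over 228 genes. What each probe matches in its transcript is not stated in the sources used here, and the contrast shows only that the probes of a gene changed unequally. Ribosomal protein genes were compared with the other genes by the difference of medians of the probe contrast, with a two-sided permutation test over genes (100000 permutations, 13 comparisons, Benjamini-Hochberg adjustment) and a two-sided exact sign test over extract pairs. For 37 °C minus 30 °C a two-sided exact permutation test over extract pairs was added after the data were seen. Genes are not independent replicates.

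Named probes were the 8 largest rises and the 8 largest falls among those called, at least 1.5-fold and of the same sign in every extract pair of the group. Named contrasts were the 10 largest and the 5 lowest by the same rule without a fold minimum. The deleted genes, up to 4 members of each list and the textbook intron genes ACT1, RPL28, RPS17A, RPS17B, RPL30, YRA1 and TUB1 were named whatever their result. Genes named under another rule are said to be so.

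Gene lists were tested with limma's camera (preset correlation 0.01, repeated with an estimated correlation) where at least 3 members were measured, on the mean of all probes of a gene. The lists held heat shock chaperones, general stress genes, ribosome biogenesis, ribosomal proteins, the spliceosome, mRNA export and mRNP proteins, reported substrates of nonsense-mediated decay, decay factors, the exosome, meiotic genes with introns, genes with 2 introns, cytoskeleton and trafficking genes with introns, glycolysis, amino acid biosynthesis, the phosphate, iron and sulfur regulons, pheromone response, genes of mating type a and alpha, haploid-specific genes, strain markers, cell wall integrity, the respiratory chain and histones. No member of the iron, sulfur and strain marker lists was measured. The general stress, phosphate, cell wall integrity and histone lists had 1 measured member each. For these, adjusting over the list alone leaves p unadjusted.

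The fits were tested on simulated data with 200 of 1536 probes changed. Of the probes changed 2-fold, 99% were recovered for npl3 deletion at 30 °C, 98% at 37 °C for 30 min, 91% for the gbp2 hrb1 double deletion at 37 °C and 88% for upf1 deletion at 37 °C for 15 min. At 1.5-fold the shares were 89%, 92%, 59% and 40%, and between 3% and 5.1% of the calls were wrong. The data themselves called only 6 probes in the double deletion at 37 °C and 17 in upf1 deletion. With so few changes the Benjamini-Hochberg threshold is stricter, so recovery there may be lower than simulated. For the probe contrast, with 60 of 228 genes changed in npl3 deletion, all 2-fold changes were recovered at both temperatures, and 73.3% (30 °C) and 66.7% (37 °C) of the 1.5-fold changes. The contrast was not simulated for the gbp2 and hrb1 deletions, so the power behind their contrast results is unknown. In a simulation of 13 lists over 981 genes, the 1 list shifted by 1.2-fold was the 1 list called. The simulated genes varied independently of each other. It therefore cannot show how often lists of correlated genes are called wrongly.

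Alternatives were arrays centred on their medians, an array-level fit with a dye coefficient, arrays of one dye orientation, batch as a random or fixed block, each comparison's own pairs, probes measured in every pair, each pair and each batch left out, and a test against a fold of 1.2. Alternatives added after the data were seen were the median of spots, other contrasts of the probes, the first or only probe of a gene in the lists, 2 lists without 1 member each (NAM7 and HMRA1), either array alone of the pair of upf1 over npl3 deletion at 30 °C, and 1 extract pair with its sign turned or left out of the shared spread, also in the sign tests over pairs. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.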

Results

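The series asked how splicing changes in budding yeast that lack SR-like proteins, a family of RNA-binding proteins with arginine-serine or arginine-glycine repeats. The strains lacked Npl3, Gbp2, Hrb1, both Gbp2 and Hrb1, the nonsense-mediated decay factor Upf1 (encoded by NAM7), or both Npl3 and Upf1. The npl3 deletion (npl3Δ) was compared with wild type in 7 extract pairs at 30 °C, 6 after 30 min at 37 °C, 2 after 15 min at 37 °C, and 1 each after 30 min at 16 °C and 45 min at 37 °C. Strains lacking gbp2 or hrb1 alone had 1 extract pair at 30 °C and 2 after 30 min at 37 °C, and the gbp2Δ hrb1Δ strain had 2 at each temperature. Strains lacking Upf1 were compared in single extract pairs. At 30 °C these were upf1Δ over npl3Δ, npl3Δ over npl3Δ upf1Δ, and npl3Δ upf1Δ over wild type and over upf1Δ. After 15 min at 37 °C they were upf1Δ over wild type, npl3Δ over upf1Δ, and npl3Δ upf1Δ over wild type and over npl3Δ, and after 30 min upf1Δ over wild type and a strain labelled as upf1Δ plus npl3Δ over npl3Δ. All values are log2 ratios of the strain written first in a comparison over the other, in both dye orientations. Comparisons with 1 extract pair have no replicate of their own and borrow the spread of the other groups.

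Probes of the deleted genes were low in most strains that lack them, and in 1 extract pair NPL3 went against the label. NPL3 fell by 1.96 ± 0.27 (SE; SD 0.22, n = 6, adjusted p = 7.32e-05) in npl3Δ after 30 min at 37 °C and by 1.45 ± 0.24 at 30 °C (SD 1.31, n = 7, adjusted p = 0.00221). The extract pair labelled npl3Δ over wild type at 30 °C, replicate 3, had NPL3 at 1.47, against the direction of its label, and NPL3 fell by 1.89 (SD 0.21, n = 6, adjusted p = 7.01e-14) without it. NPL3 was -1.29 after 15 min at 37 °C (n = 2, adjusted p = 0.0516), -1.75 at 16 °C and -0.63 after 45 min at 37 °C (1 extract pair each, adjusted p = 0.999 and 0.996). GBP2 fell by 3.55 ± 0.22 (SD 0.69, n = 2, adjusted p = 1.25e-11) in gbp2Δ hrb1Δ at 30 °C, by 3.20 at 37 °C (SD 0.88, n = 2, adjusted p = 1.4e-10), and by 3.02 in gbp2Δ at 37 °C (SD 0.06, n = 2, adjusted p = 5.17e-10). HRB1 fell by 1.67 ± 0.26 in gbp2Δ hrb1Δ at 30 °C (SD 0.70, n = 2, adjusted p = 0.000649), by 1.92 at 37 °C (SD 0.48, n = 2, adjusted p = 5.91e-05) and by 1.54 in hrb1Δ at 37 °C (SD 0.26, n = 2, adjusted p = 0.00321). In the single pair of hrb1Δ at 30 °C, HRB1 was -0.43 (adjusted p = 0.999). NAM7 fell by 3.65 ± 0.28 in upf1Δ after 15 min at 37 °C (adjusted p = 1.1e-09), by 1.55 ± 0.30 in upf1Δ at 30 °C (adjusted p = 0.00384), and by 2.32 ± 0.23 in npl3Δ upf1Δ over npl3Δ at 30 °C (adjusted p = 1.83e-07). The 30 °C value for upf1Δ rested in part on the pair of upf1Δ over npl3Δ, whose 2 arrays disagreed. Their correlation over probes was -0.052, 1 of 10 such values below 0 among 36 dye-flipped pairs. NAM7 was at -0.49 with upf1Δ in Cy5 and -2.01 in Cy3. From the first array alone NAM7 in upf1Δ at 30 °C was -1.11 and not called (adjusted p = 0.065), and from the second -1.99 (adjusted p = 2.75e-05). Without that pair it was -2.27 (adjusted p = 0.00412).

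**Figure D1:**
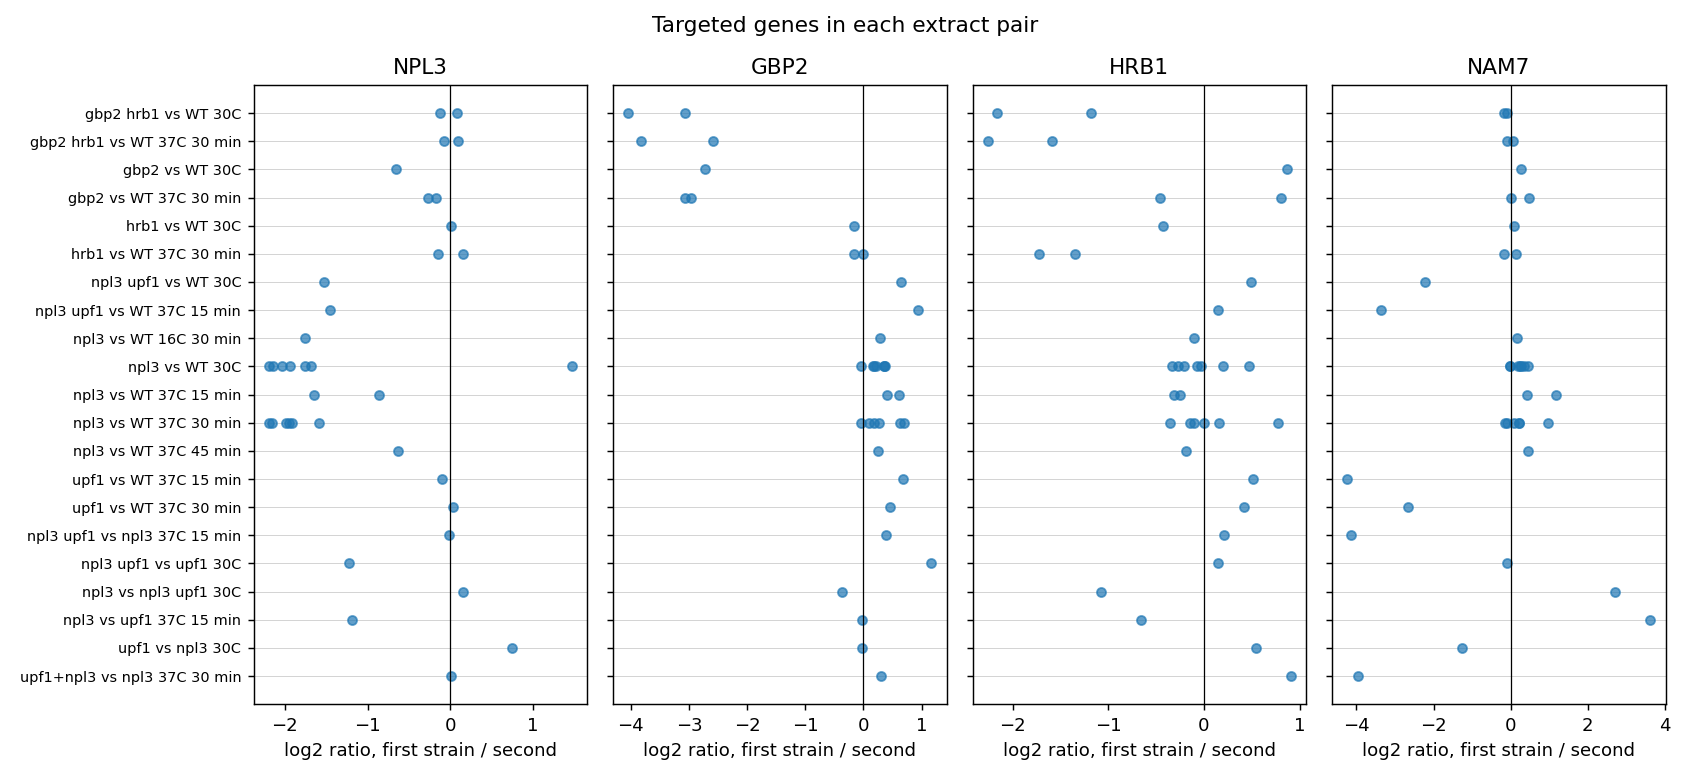
Log2 ratio (x axis, strain written first in the comparison over the other) of the NPL3, GBP2, HRB1 and NAM7 probes in each group of extract pairs (y axis), with 1 point per extract pair. In npl3Δ over wild type at 30 °C 6 of 7 points for NPL3 lie below 0 and replicate 3 lies at 1.47, while all 6 lie below 0 after 30 min at 37 °C.

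In npl3Δ at 30 °C the second printed probe was called higher than the third in 58 of 228 genes, 47 of them for ribosomal proteins (97 measured) and 11 for other genes (131 measured), and lower in 0. Of these 58 contrasts, 0 had the same sign in every pair as labelled. Among the textbook intron genes, RPS17B had a probe contrast of 0.48 ± 0.18 (SE; SD 0.69, adjusted p = 0.0492, above 0 in 6 of 7 pairs), whereas ACT1 (0.16), RPL28 (0.16), RPS17A (0.24), RPL30 (0.35), YRA1 (0.26) and TUB1 (0.07) did not pass the test. Of single probes, 51 rose and 15 fell out of 1536, and 1 of these 66 had the same sign in every pair and a change of at least 1.5-fold. The first probe of RPS14B, a small-subunit ribosomal protein gene, rose by 0.60 ± 0.10 (SD 0.23, adjusted p = 0.00221) with the same sign in 7 of 7 pairs as labelled. That became 6 of 7 with replicate 3 turned (0.54, adjusted p = 0.000647). The median probe contrast was above 0 in 6 of 7 pairs (two-sided exact sign test, p = 0.125). It was above 0 in 6 of 6 without replicate 3 (p = 0.0312) and in 7 of 7 with its sign turned (p = 0.0156). Both were chosen after the values of that pair were seen. Their outcomes were fixed in advance, since it was the only pair below 0.

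These counts at 30 °C depended on single extract pairs. The pair labelled replicate 3 correlated with the other 6 at -0.66 to -0.45 over probes, where those 6 correlated with each other at 0.41 to 0.71. With NPL3 at 1.47 in a strain labelled as lacking it, these values argue against the direction of its label, whatever the cause. The main fits keep the pair as labelled, also in the shared spread. Without this pair 246 probes and 110 contrasts were called, and with its sign turned 323 and 125. Among the textbook intron genes without it, RPS17B was at 0.71 (adjusted p = 0.000112), YRA1 at 0.42 (adjusted p = 0.00375) and RPS17A at 0.27 (adjusted p = 0.0328), all called. Those of ACT1, RPL28, RPL30 (0.44, adjusted p = 0.0517) and TUB1 were not. With its sign turned RPL30 passed as well (0.41, adjusted p = 0.0444), beside RPS17B (0.76), YRA1 (0.47) and RPS17A (0.23, adjusted p = 0.0462). Leaving out replicate 1, 2, 4, 5, 6 or 7 in place of it gave 32, 4, 7, 2, 2 and 13 probes, and 37, 29 and 28 contrasts without replicate 4, 5 and 6. The 7 pairs tested alone gave 1 probe and 0 contrasts. In the fit without replicate 3, chosen after its values were seen, RPS14B (2.71, SD 0.57, n = 6, adjusted p = 2.64e-12), RPS19B (2.20), RPS0A (1.74), RPS9A (1.73), RPL18B (1.65) and RPS18B (1.61) had the highest probe contrasts, and RPL2A (-0.43, adjusted p = 0.005) and UBC12 (-0.43, adjusted p = 0.00432) the lowest. The single probes of GCN4 (-0.94), the activator of amino acid synthesis genes, GPD1 (-0.90), a glycerol synthesis enzyme, and SRP1 (-0.76), the nuclear import receptor subunit, fell, while that of USE1 (1.74), a secretory SNARE, rose.

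After 30 min at 37 °C in npl3Δ, 203 single probes rose and 202 fell, and 119 probe contrasts rose and 3 fell, of which 87 had the same sign in every pair (86 rises and 1 fall). The rises led with ribosomal protein genes: RPS19B at 2.29 ± 0.36 (SE; SD 0.62, n = 6, adjusted p = 2.07e-05), RPL17A at 2.10 (SD 0.49, adjusted p = 1.33e-05), RPS0A at 2.09 (SD 0.81, adjusted p = 4.42e-05), RPS14B at 2.09 (SD 0.80, adjusted p = 0.00116) and RPS7B at 1.97 (SD 0.51, adjusted p = 1.33e-05), followed by RPL31A (1.85), RPL18B (1.82), RPS21B (1.77), RPS9A (1.73) and RPS10B (1.73). The fall seen in every pair was that of RRT8, a gene linked to spore wall assembly, at -0.70 (SD 0.47, n = 5, adjusted p = 0.0195), and the other called falls, named after their values were seen, were ERD2 (-0.46) and UBC12 (-0.41). Of the textbook intron genes, RPL30 (0.79, adjusted p = 0.00252), YRA1 (0.68, adjusted p = 0.000589), RPS17B (0.55, adjusted p = 0.023) and RPS17A (0.36, adjusted p = 0.00727) rose. ACT1 (0.39, adjusted p = 0.0519), RPL28 (0.17, adjusted p = 0.33) and TUB1 (0.13, adjusted p = 0.487) did not pass.

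Single probes showed which side of the contrast moved. The second probes of RPS19B (1.93, SD 0.56, adjusted p = 0.000158), RPS14B (1.91), RPS9A (1.66), RPS21B (1.55), RPS0B (1.47) and RPL17A (1.45) rose in 6 of 6 pairs, as did the probes of COS8 (1.73, SD 0.79), a subtelomeric gene, and USE1 (1.52, SD 0.91). The third probes of RPL31A (-0.97, SD 0.72, adjusted p = 0.000215) and RPS7B (-0.86, SD 0.34, adjusted p = 9.78e-05) fell. So did GCN4 (-1.04, SD 0.67, adjusted p = 0.000354), the first probe of PMI40 (-0.80, SD 0.58, adjusted p = 0.000215), a mannose metabolism enzyme, the histone gene HTA1 (-0.78, SD 0.33, adjusted p = 0.00117) and 2 unnamed probes (-0.94 and -0.88). For ACT1 the second probe rose by 0.47 (adjusted p = 0.00508), and for YRA1 the third fell by 0.53 (adjusted p = 0.0058). All 3 probes of TUB1, which encodes alpha-tubulin, fell (-0.34, -0.29 and -0.42 in print order, adjusted p = 0.0334, 0.00359 and 0.0243). Fitted on its own 6 pairs the comparison gave 156 probes, without replicate 2 it gave 268, and without batch D it gave 195 probes and 79 contrasts. Against a fold of 1.2, 67 probes passed.

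**Figure D2:**
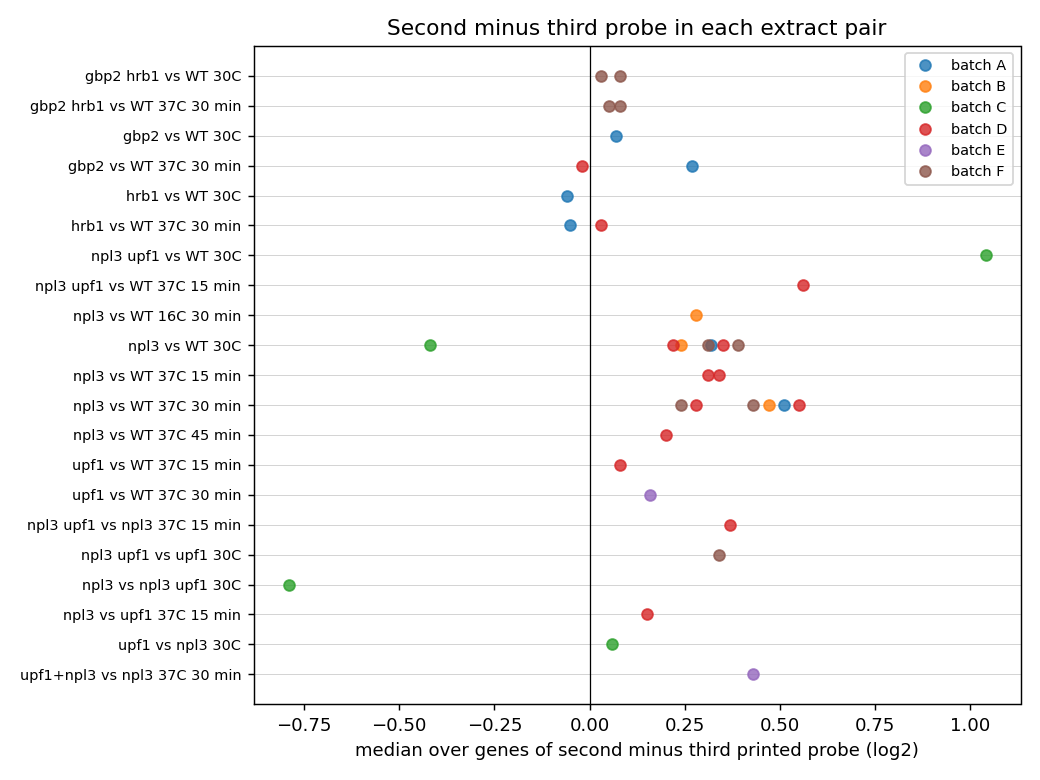
Median over 228 genes of the probe contrast (x axis, log2) for each extract pair (points, coloured by batch A to F) in each group (y axis). All npl3Δ over wild-type pairs lie above 0 except replicate 3 at 30 °C, at -0.42, and the gbp2Δ hrb1Δ pairs lie between 0.03 and 0.08.

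Averaged over all probes of a gene, 77 genes rose and 96 fell in npl3Δ after 30 min at 37 °C out of 982. Of 125 ribosomal protein genes, 18 rose and 8 fell (21 and 12 adjusted over the list alone), with RPS14B up by 0.88 ± 0.11 (SE, adjusted p = 1.96e-05), RPS9A up by 0.67 and RPP2A at -0.32 (adjusted p = 0.00556). The balance turned with the first or only probe of each gene in place of the mean, where 8 rose and 39 fell of 123 (8 and 51 adjusted over the list alone, median -0.20, camera adjusted p = 0.000128; adjusted p = 0.736 with an estimated correlation). Of 60 spliceosome genes, 4 rose and 7 fell (6 and 8 adjusted over the list alone), among them SMX2 (-0.37, adjusted p = 0.000692), PRP8 (-0.46) and PRP43 (-0.46). The mRNA export and mRNP list had 3 falls among 20 measured members (3 adjusted over the list alone), which were NAB2 (-0.51), NAB3 (-0.59) and PAB1 (-0.47), all RNA-binding proteins. Of 7 measured chaperones, the Hsp70 genes SSA3 (0.95, adjusted p = 0.00155), SSA4 (1.08, adjusted p = 0.00575) and SSA2 (0.55, adjusted p = 0.0141) rose (3 adjusted over the list alone), while HSP104 stood at 0.64 (adjusted p = 0.135). Over the 6 pairs SSA4 ranged from -0.21 to 2.39, SSA3 from -0.06 to 1.74, SSA2 from 0.07 to 1.54 and HSP104 from -0.52 to 2.81. In the test of single probes HSP104 was at 0.21 without replicate 1 (adjusted p = 0.566) and at 0.87 without replicate 6 (adjusted p = 0.0429). SSA2 was not called without replicate 1 (0.35, adjusted p = 0.0601), while SSA3 and SSA4 were called without any 1 pair. On the mean of all probes no list passed camera in this comparison, where the chaperones had the smallest p (adjusted p = 0.0778). With the first or only probe the chaperones passed (adjusted p = 0.0189; adjusted p = 0.736 with an estimated correlation).

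Smaller lists moved in single members after 30 min at 37 °C. In the cytoskeleton and trafficking list 3 genes rose and 2 fell of 15 (4 and 3 adjusted over the list alone), with GLC7, a protein phosphatase, at 0.62 and TUB1 at -0.35. Ribosome biogenesis had 1 rise and 3 falls of 17 (1 and 3 adjusted over the list alone), which were NOG2 (0.32), DBP10 (-0.29), DBP9 (-0.30) and RRP5 (-0.50). The exonuclease gene XRN1 fell by 0.37 among 6 decay factors (1 adjusted over the list alone), SKI3 by 0.28 among 20 exosome genes (0 adjusted over the list alone) and SPO1 by 0.30 among 10 meiotic genes with introns (1 adjusted over the list alone). Lists with 1 measured member gave a rise of SLT2, the cell wall kinase (0.63, adjusted p = 0.00192), and falls of HTA1 (-0.78, adjusted p = 0.00307) and GPD1 (-0.74, adjusted p = 0.0103), each called over all genes. FUS3 (1.13, adjusted p = 0.0126) and KAR4 (1.17, adjusted p = 0.0115), a kinase and a transcription factor of the mating pathway, rose, each 1 of 2 measured haploid-specific or pheromone-response genes (1 and 2 adjusted over the list alone). The alpha-specific receptor gene STE3 was at 1.64 and 1.48 in replicates 2 and 6 of this group, and the alpha list as a whole had a median of 0.76 (camera adjusted p = 0.482). No gene was called among 3 reported decay substrates, 6 genes with 2 introns, 4 respiratory chain genes, 2 glycolytic genes (TDH1 at -0.82 and PGK1 at 0.29, 1 rise and 1 fall adjusted over the list alone), 2 amino acid genes (HIS4 at -0.27, HIS5 at 0.22) or SPL2 of the phosphate list (-0.30). MFA1 and MFA2, of mating type a, stood at -0.05 and -0.10.

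The same lists at 30 °C were tested only with replicate 3 as labelled, and not without it or with its sign turned. They held 1 call over all genes, a rise of RPS14B among the ribosomal proteins (0.56 ± 0.10, SE, adjusted p = 0.00224, with 3 rises adjusted over the list alone). With the first or only probe that list was lower (median -0.06, camera adjusted p = 0.00608; adjusted p = 0.512 with an estimated correlation). Camera placed the meiotic genes with introns lower (median -0.09, adjusted p = 0.0357; adjusted p = 0.615 with an estimated correlation). It also placed the respiratory chain lower (median -0.15, adjusted p = 0.0164; adjusted p = 0.615 with an estimated correlation), with COX4 at -0.26 and 1 fall adjusted over the list alone. Adjusted over its own list alone HIS4 (-0.40) also passed, with 1 pheromone-response and 1 haploid-specific gene. GPD1 (-0.70), HTA1 (-0.43) and SLT2 (0.27), each the only measured member of its list, passed only without adjustment. Over all genes the limma adjusted p was 0.214 for HIS4, 0.0595 for GPD1, 0.214 for HTA1 and 0.316 for SLT2.

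Shorter and longer exposures were covered by fewer pairs. After 15 min at 37 °C, 23 probe contrasts rose and 1 fell in npl3Δ. RPS9A (1.89 ± 0.48, SE; SD 0.23, n = 2, adjusted p = 0.0217), RPS21B (1.63), RPS19B (1.59), RPL18B (1.43), RPL17A (1.40) and RPL35A (adjusted p = 0.00324) rose, as did YIP3 (1.49), a vesicle transport gene, and YBR219C (1.34). The fall was that of ERD2 (-0.84, SD 0.61, adjusted p = 0.0231), the receptor that retains proteins in the endoplasmic reticulum. Of single probes 64 were called (53 rises, 11 falls). Leaving out either pair left 0 or 1 contrast called, leaving out the pair of npl3Δ over upf1Δ 3 and that of npl3Δ upf1Δ over npl3Δ 10, and leaving the pair labelled replicate 3 at 30 °C out of the shared spread gave 64. In the single pairs at 16 °C and after 45 min, limma called 0 probes (22 and 42 at an unadjusted p under 0.05), and the median contrasts were 0.28 and 0.20. At 16 °C 1 contrast was called, that of RPS26A (2.15, adjusted p = 0.0428; named after its value was seen), and after 45 min limma called 0 (8 at an unadjusted p under 0.05).

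Whether loss of Npl3 acted differently at 37 °C for 30 min and at 30 °C was tested directly. Limma called 0 probes (131 at an unadjusted p under 0.05) and 0 probe contrasts (21 at an unadjusted p under 0.05), so no single gene was shown to differ between the temperatures. The median over genes of the difference in contrast, 37 °C minus 30 °C, was 0.188. Within batches that held both temperatures this median of differences was 0.23 in A, 0.21 in B, 0.06 in D and -0.03 in F. With batch as a fixed block the median was 0.095 and 0 contrasts were called (13 at an unadjusted p under 0.05). With the sign of the pair labelled replicate 3 turned it was 0.07. The chaperones were higher at 37 °C (median 0.48, camera adjusted p = 0.00431; adjusted p = 0.467 with an estimated correlation), with SSA4 at 1.22 and SSA3 at 0.81 and 2 calls adjusted over the list alone. Ribosome biogenesis was lower (median -0.18, camera adjusted p = 0.00871; adjusted p = 0.375 with an estimated correlation). The respiratory chain was higher (median 0.26, camera adjusted p = 0.000422; adjusted p = 0.208 with an estimated correlation; 2 calls adjusted over the list alone and none over all genes). NAB2 (-0.47) and 1 decay factor also passed adjusted over their lists alone. SLT2 (0.36), the only measured member of its list, passed only without adjustment. These list results used replicate 3 at 30 °C as labelled. With the first or only probe the ribosomal proteins were lower at 37 °C (median -0.13, camera adjusted p = 0.00514; adjusted p = 0.623 with an estimated correlation).

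Loss of Gbp2, Hrb1 or both gave no called probe contrast at 37 °C. In gbp2Δ hrb1Δ limma called 0 contrasts at 30 °C (4 at an unadjusted p under 0.05, median 0.054) and 0 at 37 °C (6 at an unadjusted p under 0.05, median 0.068). At 37 °C it called 0 in gbp2Δ (16 at an unadjusted p under 0.05, median 0.116) and 0 in hrb1Δ (8 at an unadjusted p under 0.05, median 0.004). The pairs of gbp2Δ differed, with a median of 0.27 in replicate 1, above 0 in 156 of 228 genes, and -0.02 in replicate 2. Leaving out replicate 2 gave 6 calls in gbp2Δ, 2 in hrb1Δ and 3 in gbp2Δ hrb1Δ at 30 °C, and leaving out either pair of gbp2Δ hrb1Δ at 37 °C gave 1. Few single probes were called, 3 in gbp2Δ and 4 in hrb1Δ at 37 °C, and 13 and 1 in their single pairs at 30 °C. Named after their values were seen, the rises were MFA2 (2.34) and GUP2 (0.96), a membrane protein gene, in gbp2Δ, and MFA2 (2.64) and the second probes of EFM5 (1.22), a methyltransferase, and KIN28 (1.02), a transcription kinase, in hrb1Δ. Beside MFA2 the markers of the opposite mating type were low in the same pairs, with STE3 at -1.22 and -3.12 and MF(ALPHA)1 at -2.09 and -4.19 in replicates 1 and 2 of gbp2Δ, and at -0.69 and -3.54 and at -3.30 and -4.96 in those of hrb1Δ. The call in hrb1Δ at 30 °C was the second probe of DTD1 (2.72), a tRNA deacylase, which also had the 1 called contrast (2.59, adjusted p = 0.00289). In gbp2Δ hrb1Δ at 30 °C the 3 called probes were GBP2, HRB1 and GAL3, a galactose sensor, at 1.53 ± 0.33 (SE; SD 1.59, n = 2, adjusted p = 0.0457). The rise of GAL3 rested on replicate 1, since without it the value was 0.40 (adjusted p = 1), and without replicate 2 the comparison gave 8 probes. At 37 °C 1 of 6 called probes rose, that of GAC1, a phosphatase subunit (1.10 ± 0.25, SE; SD 0.15, n = 2, adjusted p = 0.0498), and with GBP2 and HRB1 the invertase gene SUC2 (-1.53, SD 2.03, adjusted p = 0.0469) and the second probe of RRT8 (-1.29, n = 2, adjusted p = 0.0145) fell. The remaining call was an unnamed probe (-0.56, adjusted p = 0.0469) without the same sign in both pairs. SUC2 stood at -0.09 without replicate 1 and RRT8 at -0.37 without replicate 2, both not called, and neither was GAC1 with 1 pair (0.99 or 1.21).

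Among the gene lists in gbp2Δ hrb1Δ, the respiratory chain was higher at 37 °C (median 0.49, camera adjusted p = 8.71e-08; adjusted p = 0.0189 with an estimated correlation). No member passed over all genes, and all 4 measured, RIP1 (0.69, adjusted p = 0.0627), COX4 (0.49), QCR9 (0.48) and QCR10 (0.33), passed adjusted over the list alone. At 30 °C its median was 0.26 (camera adjusted p = 0.000424; adjusted p = 0.13 with an estimated correlation). The decay factors were not called at 30 °C (camera adjusted p = 0.123). Without NAM7, left out because the upf1 strains lack it, they were higher (median 0.07, camera adjusted p = 0.0296; adjusted p = 0.171 with an estimated correlation). Ribosome biogenesis was lower at 37 °C (median -0.19, camera adjusted p = 0.0176; adjusted p = 0.474 with an estimated correlation). With the first or only probe the ribosomal proteins were lower too (median -0.05, camera adjusted p = 0.0479; adjusted p = 0.609 with an estimated correlation). Genes of mating type alpha were lower at 30 °C (median -1.91, camera adjusted p = 3.24e-05; adjusted p = 0.0964 with an estimated correlation) and at 37 °C (median -1.54, camera adjusted p = 0.00954; adjusted p = 0.38 with an estimated correlation), with 2 and 1 falls adjusted over the list alone. MFA1 (1.32 and 1.47) and MFA2 (1.10 and 1.11) passed adjusted over the list alone at both temperatures. These values came from replicate 2, in which STE3 was -3.73 at 30 °C and -2.97 at 37 °C against -0.08 and -0.11 in replicate 1.

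The npl3Δ effect minus that of gbp2Δ hrb1Δ, both after 30 min at 37 °C, was tested as a difference. Of single probes 15 were higher and 6 lower in npl3Δ. The median over genes of the difference in the probe contrast was 0.392, and 0 contrasts were called by limma (54 at an unadjusted p under 0.05). With the pair labelled replicate 3 at 30 °C left out of the shared spread 47 contrasts and 73 probes were called, all 47 of them higher in npl3Δ, and with its sign turned 50 and 86. Probe counts fell to 4 and 9 without npl3Δ replicate 2 or 3 and to 7 without either gbp2Δ hrb1Δ pair, and contrasts numbered 3 without npl3Δ replicate 5 and 1 without gbp2Δ hrb1Δ replicate 2.

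In upf1Δ a small set of RNAs was higher after 15 min at 37 °C, estimated from 1 pair against wild type and from pairs against the other strains. Among 1536 probes 16 rose and NAM7 fell. The a-factor gene MFA2 rose by 3.58 ± 0.49 (SE, adjusted p = 4.73e-05), but genes of both mating types stood apart in the pair against wild type (MFA2 3.90, MFA1 1.74, STE3 -2.32, MF(ALPHA)1 -3.92). The second probe of RPL28 rose by 1.99 ± 0.32 (adjusted p = 0.00051), and the third RPL28 probe rose too (adjusted p = 9.71e-06), while the first stood at 0.33 (adjusted p = 0.999). RPL22B, a ribosomal protein paralog, rose in its second (1.78, adjusted p = 0.00327) and first probes (1.39, adjusted p = 0.00592). NMD4, a protein of the decay pathway (1.55), ASP3-1, an asparaginase (1.40), and CTL1, an RNA triphosphatase (1.27), also rose. RPL22B had the 1 called probe contrast, 2.06 ± 0.43 (adjusted p = 0.0152), and that of RPL28 was 0.49 (adjusted p = 0.986). Without the pair against wild type 1 probe and 0 contrasts were called, and without that of npl3Δ over upf1Δ 5 and 0. The single pair after 30 min gave 11 called probes (10 rises) and 2 contrasts, RPL22B (2.47) and IWR1 (1.52), a nuclear import factor for RNA polymerase II, named after their values were seen.

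Spliceosome genes held 3 rises in upf1Δ after 15 min (4 adjusted over the list alone), namely PRP46 (0.89, adjusted p = 0.00181), BUD31 (0.49) and PRP6 (0.57), and camera did not call the list (adjusted p = 0.0536). Of the ribosomal protein genes RPL28 (1.27) and RPL22B (0.96) rose (2 adjusted over the list alone), while the list's median was -0.05. With the first or only probe that list was lower (camera adjusted p = 0.0121; adjusted p = 0.621 with an estimated correlation) and the meiotic genes with introns higher (camera adjusted p = 0.0223; adjusted p = 0.0807 with an estimated correlation). None of the 3 measured decay substrates was called, with PPR1 at 0.21, and 1 meiotic gene with an intron rose adjusted over the list alone. The list of decay factors holds NAM7, the gene these strains lack (1 fall over all genes and 1 adjusted over the list alone), and without it the list was not called (median -0.07 over 5 genes, camera adjusted p = 0.444). Chaperones were higher (median 0.26, camera adjusted p = 0.0413; adjusted p = 0.726 with an estimated correlation; 1 rise adjusted over the list alone, over all genes 0), and ribosome biogenesis lower (median -0.14, camera adjusted p = 0.0159; adjusted p = 0.343 with an estimated correlation). The alpha list was lower (median -2.21, camera adjusted p = 0.00501; adjusted p = 0.202 with an estimated correlation; 2 falls adjusted over the list alone).

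At 30 °C upf1Δ was linked to wild type only through the other strains, in part through the pair of upf1Δ over npl3Δ, whose arrays disagreed (MFA2 0.70 and 3.90, MF(ALPHA)1 -1.40 and -6.55 with upf1Δ in Cy5 and in Cy3). In that estimate 14 probe contrasts rose, with RPL22B at 2.29 ± 0.47 (SE, adjusted p = 0.00272), RPL28 at 2.10 ± 0.30 (adjusted p = 2.32e-05), IWR1 at 2.09 ± 0.30 (adjusted p = 2.32e-05), RPS13 at 1.69, RPL30 at 1.60, RPL27B at 1.46, the meiotic gene REC107 at 1.44, RPL2B at 1.38, the proteasome gene PRE3 at 1.38 and RPS23A at 1.31. Of single probes 21 rose, and MF(ALPHA)1 and NAM7 fell. From the Cy5 array of that pair alone 42 contrasts and 62 probes were called, and from the Cy3 array 14 and 50, while without that pair 16 and 31 were called. Without the pair of npl3Δ upf1Δ over upf1Δ 3 contrasts were called, and with the pair labelled npl3Δ replicate 3 left out or turned 76 and 81.

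Removing Upf1 from npl3Δ at 30 °C raised many probe contrasts. Of 228 genes, 124 rose and 0 fell in npl3Δ upf1Δ over npl3Δ, 87 of them for ribosomal proteins and 37 others. RPL22B (3.21 ± 0.37, SE, adjusted p = 3.9e-07), RPS13 (2.65, adjusted p = 1.47e-05), RPS21B (2.63), RPS7B (2.32), RPL27A (2.31), RPS10B (adjusted p = 7.26e-05), RPL28 (2.29 ± 0.24, adjusted p = 8.27e-08), RPS29A (2.24), RPS0A (2.23) and RPS18B (2.21) led. RPL30 (2.05), RPS17B (1.48), RPS17A (0.88), ACT1 (0.82, adjusted p = 0.012) and TUB1 (0.65, adjusted p = 0.027) also rose, while YRA1 stood at 0.07 (adjusted p = 0.795). Single probes gave 178 rises and 51 falls. MFA2 (3.38 ± 0.41, SE, adjusted p = 1.95e-06) and the second probes of RPL22B (2.52), RPL28 (2.44), RPS9A (2.25), RPS10B (2.21), RPS21B (2.15) and RPL27A (1.93) rose most, with a further probe of RPS23B (2.02). The falls were led by the alpha genes MF(ALPHA)1 (-5.51, adjusted p = 7.94e-05), STE3 (-3.04), MF(ALPHA)2 (-2.50) and MATALPHA1 (-2.09), with HTA1 (-0.83, adjusted p = 0.0282) and the third probes of RPS13 (-0.85) and RPS6B (-0.79). The 1 direct pair and the loop gave these values, and without the direct pair 92 probes and 84 contrasts were called, and without npl3Δ upf1Δ over wild type 100 and 85. Turning the pair labelled npl3Δ replicate 3 gave 245 probes and 132 contrasts.

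By gene, 71 rose and 24 fell in npl3Δ upf1Δ over npl3Δ at 30 °C. Ribosomal protein genes were higher (23 rises and 3 falls of 125, 29 and 6 adjusted over the list alone, median 0.18, camera adjusted p = 3.76e-05; adjusted p = 0.243 with an estimated correlation), led by RPS9A (1.27), RPP1B (0.54), RPL28 (0.98) and RPL22B (1.07). With the first or only probe of each gene in place of the mean the list's direction turned (adjusted p = 0.284). Spliceosome genes had 6 rises and 2 falls (6 and 2 adjusted over the list alone), with PRP3 (0.50), PRP46 (0.63), HSH49 (0.66) and MSL1 (0.56). Genes with 2 introns were higher (median 0.27, camera adjusted p = 0.0345; adjusted p = 0.145 with an estimated correlation) with rises of TAD3 (0.38) and HMRA1 (0.42; 3 adjusted over the list alone). HMRA1 lies at a mating-type locus, the mating-type genes differed in this comparison, and without HMRA1 the list was not called (median 0.15, camera adjusted p = 0.118). The meiotic gene REC107 rose by 0.69 (adjusted p = 5.22e-05; 1 adjusted over the list alone), with the meiotic list called with the first or only probe (camera adjusted p = 0.0187; adjusted p = 0.0616 with an estimated correlation). The exosome (median -0.17, camera adjusted p = 0.0305; adjusted p = 0.243 with an estimated correlation) and mRNA export lists (median -0.19, camera adjusted p = 0.0305; adjusted p = 0.145 with an estimated correlation) were lower with 0 members called over all genes or adjusted over the list alone. Ribosome biogenesis was lower (median -0.20, camera adjusted p = 0.0244; adjusted p = 0.243 with an estimated correlation), with a fall of DBP10 (-0.45; 0 adjusted over the list alone). TUB1 fell by 0.44 in the cytoskeleton list (0 adjusted over the list alone). The decay factors without the deleted NAM7 were not called (median -0.08, camera adjusted p = 0.347). All 3 alpha genes measured fell (3 adjusted over the list alone, camera adjusted p = 7.96e-05; adjusted p = 0.145 with an estimated correlation), and MFA2 rose beside MFA1 at 1.23 (2 adjusted over the list alone). Adjusted over their lists alone 1 chaperone and HIS5 (0.76) passed too, and HTA1, the only measured histone gene, fell over all genes.

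After 15 min at 37 °C, 10 probe contrasts rose and 0 fell in npl3Δ upf1Δ over npl3Δ, with RPL22B at 2.23 (adjusted p = 0.00273), RPL18B at 2.12, RPS7B at 1.74, RPL21B at 1.63, RPS29B at 1.42, the transport GTPase gene SAR1 at 1.34, GLC7 at 1.31, RPL40A at 1.29, RPS16A at 1.18 and RPL23A at 0.86. Without the direct pair or that of npl3Δ upf1Δ over wild type 0 were called, and with the pair labelled npl3Δ replicate 3 left out of the shared spread 39. In npl3Δ upf1Δ over wild type 158 contrasts rose at 30 °C (median 0.881) and 95 after 15 min at 37 °C (median 0.607), and 0 fell. The strain labelled as upf1Δ plus npl3Δ over npl3Δ after 30 min at 37 °C had the same 2 genes called, RPL22B (2.43) and IWR1 (1.63; median of all contrasts 0.427), and NAM7 at -3.95 (adjusted p = 6.82e-08).

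Whether the double deletion differed from the sum of the single deletions on the log2 scale was tested as an interaction. At 30 °C 1 probe passed, the first probe of RPS9A at 1.13 (adjusted p = 0.0151), and limma called 0 contrasts (27 at an unadjusted p under 0.05). After 15 min at 37 °C limma called 0 probes (19 at an unadjusted p under 0.05) and 0 contrasts (5 at an unadjusted p under 0.05). Without the pair of upf1Δ over npl3Δ or that of npl3Δ over npl3Δ upf1Δ the probe at 30 °C was not called, and without that of npl3Δ upf1Δ over upf1Δ 3 were.

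Ribosomal protein genes had higher probe contrasts than the other genes in the comparisons on loss of Npl3, Upf1 or both. The difference of medians was 0.35 at 30 °C (0.46 against 0.11), 0.60 after 30 min at 37 °C (0.79 against 0.19) and 0.40 after 15 min at 37 °C. After 30 min 86 of 97 ribosomal protein genes and 33 of 131 others rose. It was 1.04 in npl3Δ upf1Δ over npl3Δ at 30 °C (1.43 against 0.39), 0.52 after 15 min at 37 °C, 0.38 in upf1Δ at 30 °C, 0.23 in upf1Δ after 15 min at 37 °C and 0.52 for npl3Δ minus gbp2Δ hrb1Δ. In upf1Δ it was 0.88 and 0.24 at 30 °C without the pair of upf1Δ over npl3Δ or that of npl3Δ upf1Δ over upf1Δ, and after 15 min at 37 °C 0.15 without the pair of npl3Δ over upf1Δ and 0.14 with the second probe alone. After 15 min at 37 °C, arrays with the first strain in Cy3 gave 0.18 in npl3Δ and 0.27 in npl3Δ upf1Δ over npl3Δ, and leaving out paralog pairs gave 0.65 in npl3Δ. With all pairs and arrays the permutation p in each of these 8 comparisons was 1e-05, the smallest that 100000 permutations can give (adjusted p = 1.44e-05). This p measures the spread over genes and not over extract pairs. Of these 8, only npl3Δ at 30 °C and after 30 min at 37 °C were also tested over pairs. The comparisons with upf1 strains rest on single extract pairs. The difference was 0.03 in gbp2Δ (permutation p = 0.662), -0.02 in hrb1Δ (p = 0.508), 0.05 in gbp2Δ hrb1Δ at 30 °C (p = 0.0902) and -0.01 at 37 °C (p = 1). Over extract pairs of npl3Δ it was above 0 in 6 of 6 after 30 min at 37 °C (two-sided exact sign test, p = 0.0312) and in 6 of 7 at 30 °C (exact p = 0.125). At 30 °C it was above 0 in 6 of 6 without the pair labelled replicate 3 (p = 0.0312) and in 7 of 7 with its sign turned (p = 0.0156). Both outcomes were fixed in advance, since that pair (-0.52) was the only pair below 0, so they add no support. For npl3Δ at 37 °C for 30 min minus 30 °C the difference was 0.25 over genes (permutation p = 1e-05), but over extract pairs it did not pass (mean 0.62 against 0.37, two-sided exact permutation test, p = 0.115). It was 0.11 over genes without the pair labelled replicate 3 at 30 °C and 0.10 with its sign turned (over pairs exact p = 0.214 and 0.179). Within batches it was 0.39 in A, 0.19 in B, 0.11 in D and -0.10 in F. It was 0.12 with batch as a fixed block, 0.12 without batch C and 0.43 without batch F.

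**Figure D3:**
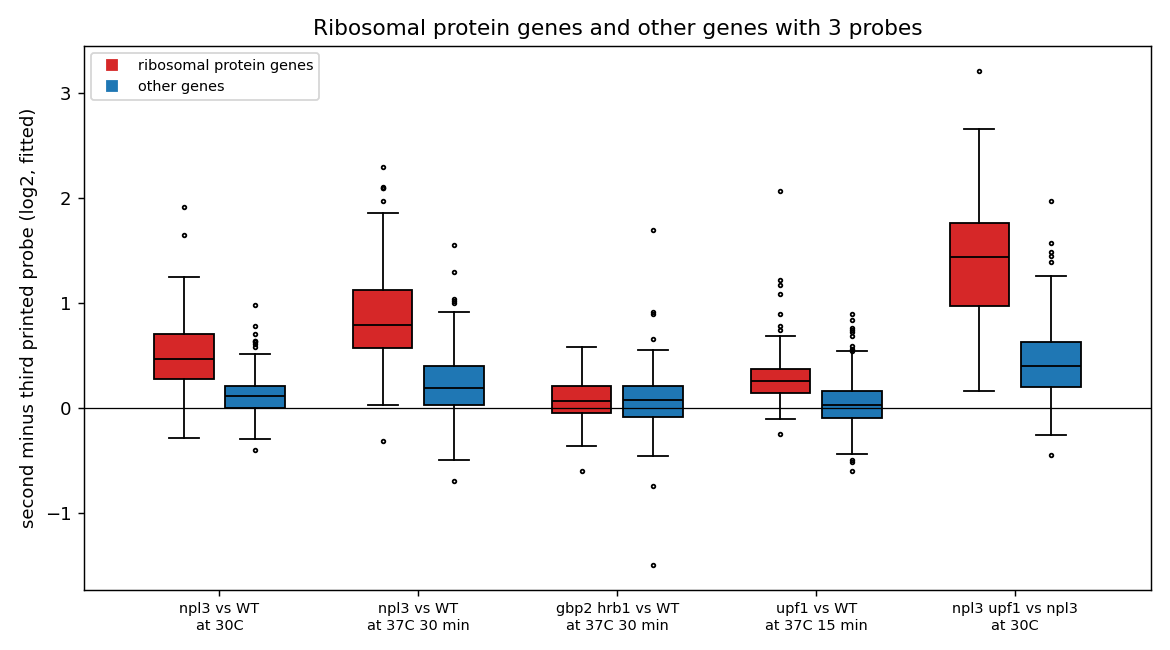
Box plots of the fitted probe contrast (y axis, log2) of 97 ribosomal protein genes (red) and 131 other genes (blue) in 5 comparisons (x axis). The ribosomal protein genes lie higher in npl3Δ at 30 °C (median 0.46 against 0.11) and at 37 °C (0.79 against 0.19), and both sets have a median of 0.07 in gbp2Δ hrb1Δ at 37 °C.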

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

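All tests in this part were chosen after the results were seen, except the interaction, which was planned. In the extract pair labelled npl3Δ over wild type at 30 °C, replicate 3, NPL3 stood at 1.47, the median probe contrast at -0.42, the difference between ribosomal protein and other genes at -0.52, and the probe contrasts of RPS17B and YRA1 at -1.06 and -0.77, each far from the other 6 pairs. In npl3Δ after 30 min at 37 °C, NAM7 was 0.96 in replicate 4, MFA1 0.49 in replicate 6 (a single array in Cy5, where replicates 2 and 3 gave 0.47 and 0.44 in that orientation), MFA2 -0.42 in replicate 1 and the probe contrast of RPS7B 2.90 in 1 pair. One pair stood apart in 9 of 66 sets of values tested, and chance sets one apart in about 5% of sets. The interaction of the npl3 and upf1 deletions at 30 °C called 1 probe, the first of RPS9A (1.13, adjusted p = 0.0151).

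The pair labelled replicate 3 ran against its label over the whole array. Dye bias was argued against by its arrays, since NPL3 was 1.38 or higher in both dye orientations (1.38 and 1.55). A ratio turned round in the deposited table or in the titles would give negative correlations with all other pairs of the group, and the highest was -0.45 (lowest -0.66). Such a turn is therefore a candidate explanation, while an exchange of extracts before labelling would look alike and stays open. No biological explanation was tested.

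Other assignments of signs to the extract pairs were counted for the npl3Δ comparisons. At 30 °C, 6 of 64 gave as many called probes (real 66, highest other 323) and 6 of 64 as many called contrasts (real 58, highest other 125), so chance was not excluded. All the larger ones turned replicate 3, which points to the structure of that pair. After 30 min at 37 °C only the real signs gave so many, 1 of 32 for probes (real 405, highest other 185) and 1 of 32 for contrasts (real 122, highest other 91). That is the smallest share that 6 pairs can give. The count also treats pairs of one batch as independent, so chance was made less likely but not excluded. For 37 °C minus 30 °C the real counts were 0 probes and 0 contrasts, which 100 of 100 drawn splits reach by construction (highest other 3 and 6), so this count decides nothing.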

How the results depend on the processing

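Among the alternatives of the main results 133 counts moved by over 1.5 times, 11 values lost their call and 0 turned, and all others kept the direction and the side of the threshold or stayed within 1.5 times the count. For 335 single probes or genes 5745 alternatives were the same, 356 weaker, 53 stronger, 250 moved and 2 reversed. Of 21 list calls 2 held with an estimated correlation, 1 of them that of the decay factors in upf1Δ, set by the deleted NAM7 and lost without it (adjusted p = 0.444), and 16 with the first printed or only probe, which gave 8 further list calls. Without NAM7 the decay factors in gbp2Δ hrb1Δ at 30 °C gained a call (camera adjusted p = 0.0296; adjusted p = 0.171 with an estimated correlation). The difference between ribosomal protein and other genes kept its call in all alternatives of the permutation over genes, at 0.24 to 0.51 in npl3Δ at 30 °C, 0.53 to 0.73 after 30 min at 37 °C, 0.18 to 0.65 after 15 min, 0.24 to 0.88 in upf1Δ at 30 °C, 0.14 to 0.28 after 15 min at 37 °C, 0.81 to 1.10 in npl3Δ upf1Δ over npl3Δ at 30 °C, 0.27 to 0.73 after 15 min at 37 °C, 0.46 to 0.65 for npl3Δ minus gbp2Δ hrb1Δ and 0.10 to 0.43 for 37 °C minus 30 °C, which did not pass over extract pairs (exact permutation p = 0.115). Alternatives chosen after seeing the data were the median of spots, all alternatives of the probe contrast, the first or only probe, the test over extract pairs, lists without NAM7 or HMRA1, sign tests without replicate 3 or with it turned, single arrays of the pair of upf1Δ over npl3Δ, and the turning or leaving out of the npl3Δ pair labelled replicate 3 at 30 °C for other comparisons. The cause was not tested for any change given here, except that fewer pairs and stricter thresholds lower counts by construction. Comparisons left with 1 pair assume that it varies like the others. No analysis paired by replicate was made because replicate numbers were given in sample order and pair nothing. The exact permutation over extract pairs ignored batch. Batch, which held both temperatures in A, B, D and F, stood in for a pairing as a fixed block. With it 37 °C minus 30 °C gave 0 probes (88 at an unadjusted p under 0.05 in limma) and 0 contrasts (13). Signal over background is unknown without scanner intensities.

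Called probes in npl3Δ at 30 °C (66) numbered 139 in the array-level fit with a dye coefficient, 106 on arrays with the first strain in Cy3, 1 on its own pairs, 1 against a fold of 1.2 and 323 with replicate 3 turned. Without batch A they numbered 1, without B 33, without C 215, without D 0 and without F 0, and leaving out 1 pair gave 2 to 246. After 30 min at 37 °C (405) its own pairs gave 156, leaving out batch D 195, a fold of 1.2 67 and leaving out 1 pair 268 to 409. In gbp2Δ hrb1Δ at 30 °C (3) its own pairs gave 0 and leaving out 1 pair 4 to 8. At 37 °C (6) arrays in Cy5 gave 14, batch as a random block 3, its own pairs 0, probes measured in all pairs 2, a fold of 1.2 2 and leaving out 1 pair 7 to 9. In upf1Δ after 15 min at 37 °C (17) the array-level fit gave 34, Cy3 6, a fold of 1.2 9 and leaving out 1 pair 1 to 5. In npl3Δ upf1Δ over npl3Δ at 30 °C (229) Cy5 gave 114, a fold of 1.2 100 and leaving out 1 pair 92 to 246. For 37 °C minus 30 °C (0) the array-level fit gave 1 and leaving out 1 pair 0 to 2. For npl3Δ minus gbp2Δ hrb1Δ (21) the array-level fit gave 68, Cy5 1, Cy3 8, its own pairs 7, a fold of 1.2 2, the median of spots 13, replicate 3 turned 86, that pair left out of the spread 73 and leaving out 1 pair 4 to 21. For the interaction at 30 °C (1) the array-level fit gave 3, Cy5 0, Cy3 0, a fold of 1.2 0, replicate 3 turned 2 and leaving out 1 pair 0 to 3.

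Called contrasts in npl3Δ at 30 °C (58) numbered 0 on its own pairs, 105 without batch C, 0 without D, 0 without F, 125 with replicate 3 turned and 28 to 110 with 1 pair left out. After 30 min at 37 °C (122) they numbered 79 without batch D. After 15 min (24) the array-level fit gave 41, Cy3 37, batch as a random block 7, its own pairs 74, the second probe alone 43, replicate 3 turned 64, that pair left out of the spread 64 and leaving out 1 pair 0 to 10. In gbp2Δ at 37 °C (0) the array-level fit gave 1, Cy3 8, its own pairs 2, the second probe alone 5 and leaving out 1 pair 0 to 6. In hrb1Δ at 37 °C (0) the second probe alone gave 2 and leaving out 1 pair 0 to 2. In gbp2Δ hrb1Δ at 30 °C (0) Cy5 gave 1 and leaving out 1 pair 0 to 3, and at 37 °C (0) Cy5 gave 2, Cy3 2, second minus first probe 1, the second probe alone 1, the median of spots 1 and leaving out either pair 1. In upf1Δ at 30 °C (14) the array-level fit gave 31, Cy3 4, second minus first probe 5, the second probe alone 33, replicate 3 turned 81, that pair left out 76, the Cy5 array alone of upf1Δ over npl3Δ 42 and leaving out 1 pair 3 to 16. In upf1Δ after 15 min at 37 °C (1) the array-level fit gave 2, Cy5 0, second minus first probe 0, the second probe alone 3, the median of spots 2, replicate 3 turned 2, that pair left out of the spread 3 and leaving out either pair 0. In npl3Δ upf1Δ over npl3Δ after 15 min at 37 °C (10) the array-level fit gave 29, Cy5 21, Cy3 2, second minus first probe 3, the second probe alone 39, replicate 3 turned 39, that pair left out of the spread 39 and leaving out 1 pair 0 to 9. For npl3Δ minus gbp2Δ hrb1Δ (0) the array-level fit gave 30, Cy5 2, its own pairs 19, second minus first probe 3, the second probe alone 14, replicate 3 turned 50, that pair left out of the spread 47 and leaving out 1 pair 0 to 3. For 37 °C minus 30 °C (0) leaving out 1 pair gave 0 to 1, and for the interaction at 30 °C (0) the array-level fit gave 1.

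NPL3 in npl3Δ at 30 °C was -1.47 on its own pairs (adjusted p = 0.322), -1.40 without batch A (adjusted p = 0.0615), -1.21 without D (adjusted p = 0.663) and -1.25 without F (adjusted p = 0.426), all without a call. In gbp2Δ hrb1Δ GBP2 lost its call on its own pairs at 30 °C (-3.55) and at 37 °C (-3.20), as did HRB1 (-1.67 and -1.92), and HRB1 also on Cy5 arrays (-1.12 and -0.98) and at 30 °C without replicate 2 (-1.18, range -2.16 to -1.18). Values that turned were ERD2 in npl3Δ after 15 min at 37 °C with the second probe alone (0.14) and the ribosomal protein list in npl3Δ upf1Δ over npl3Δ at 30 °C with the first or only probe (camera adjusted p = 0.284). GAL3 in gbp2Δ hrb1Δ at 30 °C was also counted as reversed on Cy3 arrays. At 0.00 it had lost its rise there and did not clearly fall.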

Other observations

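All tests in this part were chosen after the results were seen. The 2 arrays of prp2-1, a mutant of the helicase that acts before the first step of splicing, had no dye flip and are given as values. Against prp5-1 the median was 0.17 for the first printed probes, 0.38 for the second and -0.04 for the third, and the median probe contrast was 0.35, above 0 in 156 of 228 genes. Against prp8-1 these medians were 0.17, 0.31 and -0.11, with a contrast of 0.38, above 0 in 160 genes. The contrast of RPL28 was 1.19 and 0.99, that of ACT1 -0.02 and -0.22, and that of RPL30, whose splicing its own protein represses, -1.21 and -0.29. GBP2 stood at -1.08 and 1.51.

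Genes of the mating types moved with single extract pairs. In replicate 2 of gbp2Δ hrb1Δ the pheromone genes MFA2 and MF(ALPHA)1 stood at 2.27 and -5.83 at 30 °C, and STE3 at -3.73, against -0.08 in replicate 1. An effect of the deletions themselves was argued against in gbp2Δ hrb1Δ, since STE3 differed between pairs of one genotype by at least 2.85 at one temperature (3.65 at the other). In 8 of 8 gbp2Δ, hrb1Δ and gbp2Δ hrb1Δ pairs with STE3 beyond 0.5, MFA2 went the other way and MF(ALPHA)1 the same way, so the strains of a pair may differ in mating type. The upf1Δ strains, in which MFA2 might also rise through lost decay, had the same pattern. STE3 and MF(ALPHA)1 were -2.51 and -5.00 in upf1Δ over wild type after 30 min at 37 °C. They were -2.26 and -5.96 in npl3Δ upf1Δ over wild type at 30 °C, but -0.12 and -0.01 in npl3Δ upf1Δ over upf1Δ. These falls argue against lost decay of MFA2 as the whole cause. The upf1Δ strains may thus also differ in mating type from the others, which was not tested.

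The rise of the second printed probes over the third in npl3Δ has candidate technical and biological explanations. The print row of the probes was argued against as the whole cause by the contrast of second with first probes. Its median was at least 0.20 (up to 0.61) in every pair after 30 min at 37 °C. First and second probes of a gene lie in different blocks of the print, so an effect of the block stays open. The gbp2Δ hrb1Δ pairs with STE3 below -2 had a median contrast of at most 0.05, against at least 0.24 in the npl3Δ pairs at 37 °C for 30 min. They cannot decide on a mating-type difference, since STE3 ran the other way in npl3Δ, up to 1.64. In npl3Δ replicates 1 and 3 at 37 °C for 30 min, STE3 was -0.17 and 0.10 and the median contrast 0.47 and 0.28. For these pairs the values argue against a mating-type difference as the whole cause. In replicates 2, 4 and 6, with STE3 at 1.64, 0.98 and 1.48, MFA2 of the opposite mating type stood at 0.04, -0.04 and 0.01. In gbp2Δ hrb1Δ replicate 2 at 37 °C it was 2.46. The values of MFA2 argue against a mating-type difference in these npl3Δ pairs too. Replicate 1 of gbp2Δ at 37 °C, with STE3 at -1.22, had a median contrast of 0.27. That second probes lie in introns, so that unspliced RNA may have risen, cannot be told apart from other causes. In upf1Δ, unspliced RPL28 RNA is expected. After 15 min at 37 °C its second probe was at 1.99 and the third rose as well, with a probe contrast of 0.49. At 30 °C the second probe of RPL28 did stand above the third. The contrast was 2.10 in upf1Δ and 2.29 in npl3Δ upf1Δ over npl3Δ. These values rest on a single gene and on single extract pairs of the upf1 strains, and the sources used here give no probe types.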
